A study of Ulmus minor with 54 samples.

How the data were processed

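The series holds RNA-seq of 54 leaf libraries of Ulmus minor in 18 groups of 3, of which 18 libraries form the priming set and 36 the triggering set. Per the labels' protocols, leaf tissue around the treated site was frozen, RNA was extracted with phenol, and libraries were made from polyadenylated RNA. The authors deposited raw read counts for 237477 assembled sequences, named as contigs or scaffolds, with 1 column per library. Base calling with CASAVA and read trimming with Trimmomatic 0.33 are named in the submitters' processing notes. The assembly, the aligner and the counting program are not given in the sources used here, nor whether strand was used in counting. Reads of overlapping, antisense or closely related sequences thus cannot be told apart, and 1 gene can be split over several sequences. Every sequence is called a transcript here.

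Columns were matched to libraries by the number that the labels give each sample, and 0 columns of the table were left out. The values were whole numbers with a different total in each library, from 14667334 in CT 24 h replicate 1 to 93878963. Within groups, all 54 pairs of libraries were compared by a chi-square of their counts over sequences with at least 10 reads in the pair. The smallest chi-square per degree of freedom was 9.48, so no 2 columns of a group hold the same library.

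The groups, the main comparisons, the list tests, the alternatives and the rule for named transcripts were fixed before the data were examined. The tests between times, of harvest time and the permutation tests of sequence groups were not part of that plan. Each set was filtered with filterByExpr on its groups (minimum count 10, minimum total count 15), which left 126737 transcripts in the priming set and 147417 in the triggering set. Libraries were scaled with TMM and fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest, in R 4.3.3), with 1 mean per group and all libraries of a set in 1 fit, so that its groups share 1 estimate of the spread. A transcript was called at a Benjamini-Hochberg adjusted p of at most 0.05 over all tested transcripts of a comparison, with no minimum fold. The comparisons were P against C in the priming set, and CT against CC, PT against PC, PC against CC, PT against CT and the interaction in the triggering set, each at 1, 6 and 24 h. SEs are the log2 fold change divided by the square root of the F value. Levels are counts-per-million (CPM) of the deposited counts over TMM-scaled library sizes of the set, so levels of the priming and triggering sets were scaled separately.

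Lists of called transcripts were tested in other comparisons with camera, at a preset correlation of 0.01 and at an estimated one, and with fry (limma 3.58.1), on log2 CPM with a prior count of 2. The adjusted p of a list test is over the 27 or 30 tests of its family. Lists from the mean of both feeding responses are independent of PT against CT and of the interaction in a balanced design. The uneven spread of CT 24 h replicate 1 weakens this at 24 h, so these tests were repeated without that library. Overlaps of calls are given beside the number that independent lists of those sizes would share. Reads-per-million of sequence groups (RPM, not TMM-scaled) were compared with 2-sided exact permutation tests of the mean log10 of RPM plus 0.1 in 9 against 9 libraries, which cannot give a p below 4.11e-05. Some of these 25 tests had an outcome set by the choice of sequences, such as P against C for sequences chosen high in P. Their small p values make the adjusted p of the other tests too small, so the unadjusted p matters more there.

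By the rule for named transcripts in a table without gene names, the text names, for P against C, CT against CC and PT against CT, up to 2 transcripts that rose and up to 2 that fell, with the smallest p over the 3 times, among called transcripts with a mean log2 CPM of at least 1 and groups that do not overlap. Transcripts behind a count of 5 or fewer are named in addition, chosen after their values were seen. Lists of gene functions that had been planned could not be applied, since the identifiers come without names.

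The procedure was tested on simulated data drawn from the real means and library sizes with 200 changed transcripts. For P against C at 1 h, with 122329 transcripts, it recovered 10.0% of those changed 2-fold, 78.0% of those changed 4-fold and 100% of those changed 8-fold or 16-fold, with 8 false calls. For CT against CC at 24 h, with 139757 transcripts, the shares were 8.00%, 86.0%, 100% and 100%, again with 8 false calls. Changes of 2-fold were thus mostly out of reach in these 2 comparisons. The changed transcripts were drawn from those with a mean of at least 1 CPM, and the simulated spread depended on the mean level alone. Recovery in the real data, which hold rarer transcripts and a library of odd makeup, can be lower. Neither depth nor the number of libraries was varied.

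Fixed in advance, the analysis was repeated with DESeq2 size factors in place of TMM, no filter beyond 1 read, DESeq2 1.42.0 with its Wald test, the replicate number as a block, only the compared groups in the fit, and each library of the compared groups left out in turn. For lists, the 200 transcripts with the smallest p per direction replaced the called ones. Sequences seen in fed leaves alone were also counted at minimums of 1 and 10 reads. Chosen after the data were seen were leaving CT 24 h replicate 1 out of the whole triggering fit, with and without the block, leaving P replicate 1 out at all 3 times, and the rule for sequences tied to the egg treatment. The replicate numbers are not said to mark trees or days. Same-numbered libraries deviated together, with every correlation above 0.1, only in PC against CC at 1 h (0.108 to 0.378), so the blocked value stands beside that count.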

Results

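Polyadenylated RNA was sequenced from leaves of the field elm, Ulmus minor, grown from a clonal in vitro culture, in a study of how insect egg deposition alters the later response of the leaf to feeding larvae. Egg deposition was simulated by scratching off a strip of leaf epidermis and covering the wound with oviduct secretion of gravid females of the elm leaf beetle, a specialist herbivore of elms. The untreated control leaves were not scratched, so the wound and the secretion act together in every comparison of treated with untreated leaves. The priming set held 18 libraries, from untreated leaves (C) and leaves with simulated eggs (P) harvested 1, 6 and 24 h after treatment. The triggering set held 36 libraries from leaves harvested 7 days later, 1, 6 and 24 h after 5 neonate larvae had been placed on each fed leaf. Its 4 treatments were no stimulus (CC), simulated eggs alone (PC), larvae alone (CT) and simulated eggs followed by larvae (PT). Each of the 18 combinations of treatment and time had 3 libraries. The labels do not say whether these came from separate trees, so p-values measure the spread between the libraries, which may be partly technical.

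Reads had been counted on 237477 assembled sequences, of which 216675 were contigs and 20802 scaffolds. The deposited table does not pair their identifiers with gene names, so transcripts are given here by identifier, level and response, and no gene function is assigned. The total count was 14667334 in replicate 1 of CT at 24 h and between 28916592 and 93878963 in the other libraries. That library also stood apart in makeup. It held reads of 62026 sequences, against 176736 to 221423 in the others, and 80.3% of its reads lay in its 10 most abundant sequences. In the priming set, replicate 1 of P was the least alike to the other libraries at each time. Its median rank correlation with them was 0.825, 0.830 and 0.831 at 1, 6 and 24 h, against at least 0.850 in the other priming libraries. The 10 most abundant sequences of each library took 52.8% ± 26.9 of its reads in CT at 24 h and 40% ± 16.5 in PT at 6 h, but 19.3% ± 13.5 in CT at 6 h and 10.4% ± 4.05 in PT at 1 h (SD, n = 3 each). In CC they took 15.8% ± 6.71 at 24 h and 18.3% ± 13.5 at 6 h (SD, n = 3 each).

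**Figure D1:**
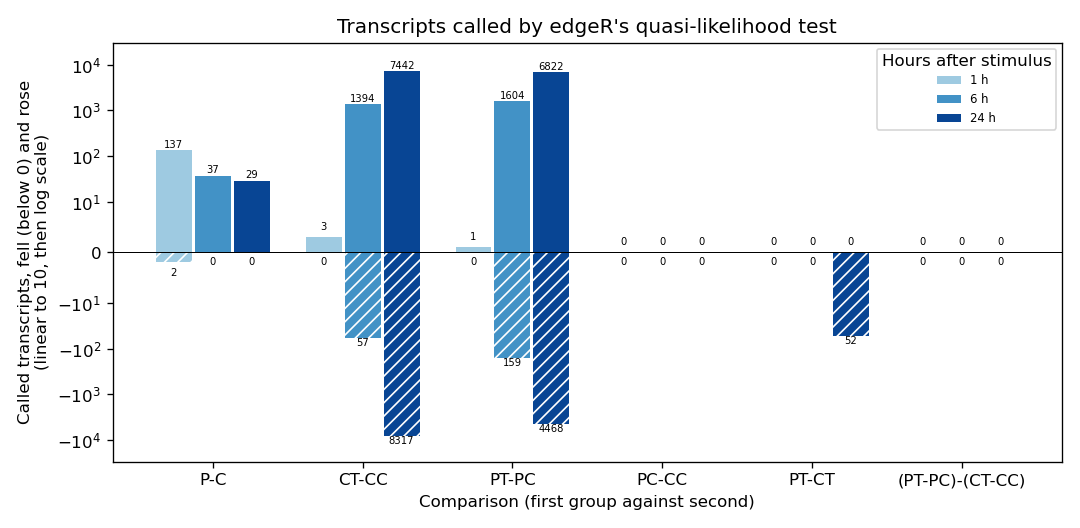
Numbers of transcripts that rose (bars above 0) or fell (hatched bars below 0) in each comparison at 1, 6 and 24 h after the stimulus, on an axis that is linear up to 10 and logarithmic beyond. Feeding changed 15759 transcripts in CT against CC at 24 h, while PC against CC stood at 0 at each time.

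The first comparison, P against C, asked how elm leaves respond to simulated eggs within a day. The calls were few and almost all of them rises. At 1 h, 137 transcripts rose and 2 fell, at 6 h 37 rose, and at 24 h 29 rose, out of 126737 tested with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of at most 0.05. The rises were steep, with a median log2 fold change of 3.94 at 1 h, 5.08 at 6 h and 9.80 at 24 h. Of them, 120, 36 and 29 reached at least 4-fold. Of these risers, 6, 3 and 2 had 0 reads in all 3 C libraries of their time. With those set to a lower bound from 3 reads over the group, the medians were 3.90, 5.08 and 9.80.

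Many of the risers were nearly silent in untreated leaves. A level under 0.1 CPM (counts-per-million) in the pooled reads of the 9 C libraries was found for 18.2% of the risers of 1 h, 43.2% of those of 6 h and 69.0% of those of 24 h. The share was 2.10% over all tested transcripts. This contrast decides nothing about the risers, since a transcript so low in C passes the filter mainly through a P group where it is high. The 3 lists overlapped little. At both 1 and 6 h 8 transcripts rose, where independent lists would share 0.0400, and 0 risers of 24 h had risen at an earlier time. The response itself was not shown to differ between times, since edgeR's quasi-likelihood test called 0 transcripts for each pair of times, with 5739 at an unadjusted p of at most 0.05 for 6 against 1 h, 5214 for 24 against 6 h and 4481 for 24 against 1 h. Of the 29 risers of 24 h, 16 belonged to a group of 635 sequences that took 1141 to 20438 RPM (reads-per-million) in the 3 P libraries of 24 h and at most 5.49 in any C library. The group was formed after the data were seen, from sequences high in P and low in C. Its levels and its overlap with the risers were thus largely built into the choice.

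Scaffold14419 was the riser with the smallest p at 1 h. Its level was 13.4 ± 6.16 CPM in P and 0.217 ± 0.106 CPM in C (SD, n = 3 each), a log2 fold change of 5.98 ± 0.55 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.98e-04). In P it stood at 0.176 ± 0.0979 CPM at 6 h and 1.85 ± 0.734 CPM at 24 h (SD, n = 3 each). C607447 rose at 24 h, to 22 ± 14.9 CPM in P from 0.350 ± 0.201 CPM in C (SD, n = 3 each), with a log2 fold change of 5.98 ± 0.68 (SE; same test, Benjamini-Hochberg adjusted p = 0.0151). Scaffold197, an abundant transcript, fell at 1 h by 0.91 ± 0.15 (SE) on the log2 scale, to 32.8 ± 2.76 CPM from 61.8 ± 0.867 CPM (SD, n = 3 each; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0306). The other faller, C212663, is named because the count was small, after its values were seen. It lay at 0.117 ± 0.0242 CPM in P and 0.390 ± 0.0424 CPM in C (SD, n = 3 each), with an adjusted p of 0.0366 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

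These counts were unstable when 1 library was left out, but no single library carried them. Fewer libraries also leave fewer degrees of freedom, and the cause of the lost calls was not tested. Without C replicate 1, 2 or 3 the count of 1 h was 1, 4 and 0, and without P replicate 1 or 3 it was 53 and 261. Scaffold14419 had an adjusted p of 0.0519 without C replicate 3 (at most 0.0519 over its alternatives) and scaffold197 between 0.0574 and 0.238 without any 1 of the 6 libraries. The call of C212663 was also lost without any 1 of them (adjusted p from 0.0548 to 0.238). The fold changes of the named transcripts moved little over all alternatives. On the log2 scale they were at least 5.74 for scaffold14419 and 5.33 to 6.48 for C607447. They were -0.97 to -0.86 for scaffold197 and -1.78 to -1.55 for C212663. At 6 h the count was 0 without C replicate 2 or 3 or P replicate 1 or 2. At 24 h it was 0 without any 1 of the C libraries, which also ended the call of C607447 (adjusted p from 0.157 to 0.276), and it was 102, 738 and 10 without P replicate 1, 2 and 3. DESeq2's Wald test called 1515, 498 and 234 transcripts at the 3 times, of which 63, 32 and 10 fell.

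The second comparison, CT against CC, asked how leaves without earlier eggs respond to larvae. There were 3 risers and 0 fallers at 1 h, 1394 risers and 57 fallers at 6 h and 7442 risers and 8317 fallers at 24 h, out of 147417 transcripts tested with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of at most 0.05. The count of 1 h varied with the method and the libraries, as DESeq2's Wald test called 556 and edgeR's quasi-likelihood test called 245 without CT replicate 1. At 6 h the calls were mostly rises, with a median log2 fold change of 3.77 among the risers and -1.65 among the fallers. With CT 24 h replicate 1 left out, 1778 rose and 169 fell at 6 h. At 24 h rises and falls were both common, and rises were the larger, at a median of 2.32 against -1.40. Which direction was the more common depended on the fit: with only the compared groups in it 2061 rose and 484 fell, and without CT 24 h replicate 1 7916 rose and 6398 fell. Of the 1394 risers of 6 h, 1141 were also called as risers at 24 h (70.4 shared by independent lists) and 0 as fallers.

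At 24 h, 4362 risers and 1742 fallers had changed at least 4-fold. With the 425 risers and 154 fallers that had 0 reads in the lower group set to a bound from 3 reads over the group, these numbers were 4360 and 1664 and the medians 2.32 and -1.40. At 6 h, 234 risers had 0 reads in CC, and the median with bounds was 3.54. The pooled level of the 18 unfed libraries was under 0.1 CPM for 38.5% of the risers of 6 h and 25.1% of those of 24 h. The share over all tested transcripts of this set was not computed. Such transcripts pass the filter mainly through a fed group where they are high, so these shares decide nothing. RNA of the larvae was not told apart from that of the leaf. The difference of the response between times passed the same test for 860 transcripts in 24 against 1 h (499 higher and 361 lower at 24 h), 12 in 24 against 6 h and 1 in 6 against 1 h. Without CT 24 h replicate 1 these counts were 1174, 3 and 1.

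C80997 and C242117 were the risers with the smallest p among those that met the naming rule, which asks for a mean log2 CPM of at least 1 and groups that do not overlap. C242117 reached 42.4 ± 19.4 CPM in CT at 24 h (SD, n = 3), with 4222 reads, against 1 read in CC, a ratio of pooled levels of 8654 with an exact 95% counting interval from 1552 to 341882 (log2 fold change 12.34 ± 0.99, SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.56e-08). C80997 stood at 23.5 ± 17.1 CPM in CT at 24 h (SD, n = 3), with 2597 reads against 1 in CC, a ratio of 5323 with an interval from 955 to 210326 (log2 fold change 11.52 ± 0.95, SE; same test, Benjamini-Hochberg adjusted p = 1.52e-08). Both intervals cover counting error only. The ratios hold against CC alone, since C80997 stood at 1.48 ± 1.60 CPM (SD, n = 3; 252 reads) and C242117 at 0.125 ± 0.122 CPM (SD, n = 3; 21 reads) in C at 24 h of the priming set. The fallers named by the same rule were scaffold6788, at 19.1 ± 2.33 CPM in CT and 71.7 ± 4.19 CPM in CC (SD, n = 3 each; log2 fold change -1.90 ± 0.20, SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.75e-07), and scaffold1833, at 3.42 ± 1.02 and 20.5 ± 6.54 CPM (SD, n = 3 each; log2 fold change -2.55 ± 0.30, SE; same test, Benjamini-Hochberg adjusted p = 1.21e-06). The 3 risers of 1 h, named because the count was small, after their values were seen, were C400939, C605647 and scaffold4263, with log2 fold changes of 3.40, 3.87 and 4.25 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0343, 0.0343 and 0.0357). Each of them was also called as a riser at 6 and 24 h in both CT against CC and PT against PC. Scaffold4263 was among the risers of P against C at 1 h.

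**Figure D2:**
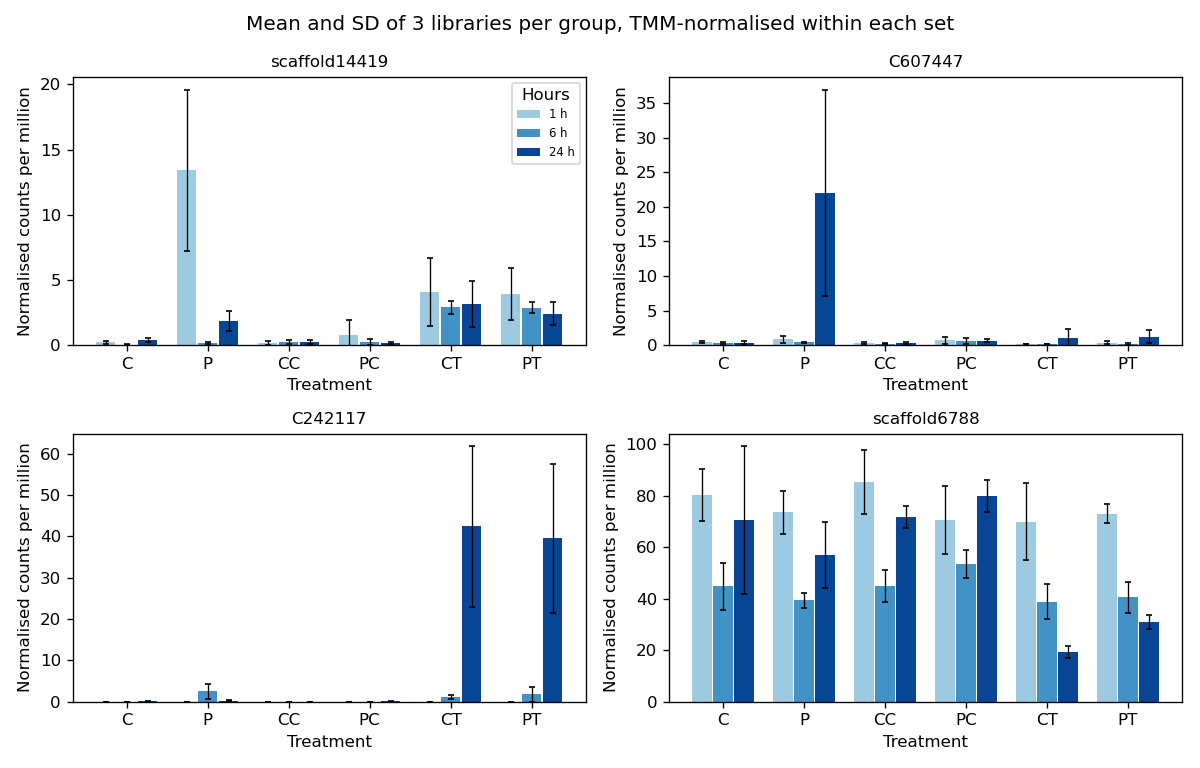
Normalised CPM of 4 transcripts in the 6 treatments at 1, 6 and 24 h, as mean and SD of 3 libraries on linear axes that start at 0. Scaffold14419 peaked in P at 1 h at 13.4 CPM, and C607447 in P at 24 h at 22 CPM. C242117 stood at 42.4 CPM in CT and 39.5 CPM in PT at 24 h, and scaffold6788 was lower in CT and PT at 24 h than in CC and PC.

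The 1 h count was 245 without CT replicate 1, 15 without CT 24 h replicate 1, 1 without CT replicate 2, and 0 without CT replicate 3 or any 1 CC library, where the 3 transcripts had adjusted p values from 0.101 to 0.356. Over all alternatives their log2 fold changes at 1 h were 3.14 to 3.72 for C400939, 3.02 to 4.16 for C605647 and 3.94 to 4.78 for scaffold4263. At 6 h the count was 593, 555 and 684 without CC replicate 1, 3 and 4 and 813 without CT replicate 1. At 24 h it was 8891 without CC replicate 2. Of the 7916 risers and 6398 fallers without CT 24 h replicate 1, 5708 and 5754 were shared with the full set.

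The third comparison, PT against PC, asked the same of leaves that had carried simulated eggs 7 days before. There was 1 riser at 1 h, 1604 transcripts rose and 159 fell at 6 h, and 6822 rose and 4468 fell at 24 h, out of 147417 tested (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p of at most 0.05). The numbers of 6 h were 2468 and 632 without CT 24 h replicate 1, and those of 24 h 9488 and 7368. The median log2 fold change was 3.34 for the risers and -1.43 for the fallers of 6 h, and 2.36 and -1.38 for those of 24 h. Of the 1604 risers of 6 h, 1259 were called as risers again at 24 h (74.2 for independent lists). C242117 stood at 39.5 ± 18.1 CPM and C80997 at 26.2 ± 0.0317 CPM in PT at 24 h (SD, n = 3 each), and scaffold6788 at 30.9 ± 2.73 CPM against 80.0 ± 6.19 CPM in PC (SD, n = 3 each).

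At 6 h, 213 risers and 3 fallers had 0 reads in the lower group, and with bounds the medians were 3.27 and -1.43. At 24 h these were 401 risers and 17 fallers, with medians of 2.35 and -1.38. The single riser of 1 h was C376501, named after its values were seen because the count was small (log2 fold change 2.63). The response differed between times for 848 transcripts in 24 against 1 h (719 higher and 129 lower at 24 h), 46 in 6 against 1 h and 3 in 24 against 6 h by edgeR's quasi-likelihood test. Without CT 24 h replicate 1 these counts were 1766, 77 and 4.

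The 1 h count was 0 without PC replicate 2 or PT replicate 1, 2 without PC replicate 3, 178 without PT replicate 2, 547 without PC replicate 1 and 153 without CT 24 h replicate 1. C376501 had adjusted p values from 0.0628 to 0.154 without PC replicate 2 or 3 or PT replicate 1 or 3. Its log2 fold change was 2.48 to 2.89 over all alternatives. At 6 h the count was 708, 576 and 681 without PC replicate 1, 2 and 3, 993 and 1153 without PT replicate 1 and 2, and 3100 without CT 24 h replicate 1. At 24 h it was 6531 and 5956 without PC replicate 1 and 2 and 5177 without PT replicate 3.

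Feeding raised many of the same transcripts with and without earlier eggs. At 6 h, 861 transcripts rose in both CT against CC and PT against PC, where independent lists would share 15.2, and 0 fell in both. Without CT 24 h replicate 1, 12 fell in both at 6 h (0.684 for independent lists). At 24 h, 4215 rose in both (344 for independent lists) and 2644 fell in both (252 for independent lists). The 2 comparisons share no library. Across all tested transcripts, which are not independent replicates, the log2 fold changes of both had a Pearson r of 0.34 at 1 h, 0.43 at 6 h and 0.66 at 24 h. Slopes of PT against PC on CT against CC were 0.37, 0.39 and 0.56. Error in the CT against CC values pulls such slopes down, so they do not show a weaker response after earlier eggs.

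The fourth comparison, PC against CC, asked whether simulated eggs had left a trace in unfed leaves after 7 days. No single transcript passed at any time. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 147417 at 1, 6 and 24 h, with 3978, 4514 and 4583 at an unadjusted p of at most 0.05, and DESeq2's Wald test called 95, 111 and 34. With the replicate number as a block, 2 transcripts rose at 1 h, the only comparison in which every same-numbered pair of libraries correlated above 0.1. Without PC replicate 2 the count of 1 h was 2, and without CC replicate 4 that of 6 h was 1. Scaffold14419, which had led the early response to simulated eggs, stood at 0.781 ± 1.15 CPM in PC and 0.181 ± 0.157 CPM in CC at 1 h (SD, n = 3 each).

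The fifth comparison, PT against CT, and the interaction, the difference between the feeding responses with and without earlier eggs, asked the study's main question. At 1 and 6 h edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 transcripts between PT and CT, with 5040 and 6000 at an unadjusted p of at most 0.05. DESeq2's Wald test called 25 and 5. A lack of calls does not show a lack of difference, and recovery was not simulated for PT against CT. At 24 h, 52 transcripts were lower in PT than in CT and 0 were higher (9385 at an unadjusted p of at most 0.05; DESeq2 called 229 lower and 16 higher). The interaction gave 0 transcripts at 1, 6 and 24 h, with 2963, 6665 and 6812 at an unadjusted p of at most 0.05 and 14, 99 and 35 by DESeq2's Wald test.

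The 52 calls rested on 1 library. C573981 had 4296 reads in CT at 24 h, with levels from 0.102 to 970 CPM, and 0 reads in PT. On the pooled levels this is at least 3067-fold lower, counting 3 reads over the group as the floor (log2 fold change -17.11 ± 2.88, SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0281). C614091 had a log2 fold change of -5.70 ± 1.10 (SE; same test, Benjamini-Hochberg adjusted p = 0.0404). Replicate 1 of CT held 99.95% of the CT reads of the median called transcript. Without it, edgeR's quasi-likelihood test called 0 transcripts (5402 at an unadjusted p of at most 0.05) and gave C573981 and C614091 a Benjamini-Hochberg adjusted p of 1.00. The count was 627 and 410 without CT replicate 2 and 3 and 0 without any 1 PT library, where both transcripts had an adjusted p from 0.331 to 0.405.

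The transcripts that had risen after simulated eggs were then followed into the triggering set, in other libraries and 7 days later. Those that rose at 1 h in P moved strongly with feeding. Of 137, 100% had a higher mean log2 CPM in CT than in CC at 1 h, 97.1% at 6 h and 93.4% at 24 h, with median differences of 2.07, 2.70 and 2.91. The 37 risers of 6 h had median differences of 4.02 at 6 h and 5.64 at 24 h. All 5 of these set tests passed in camera with a preset correlation of 0.01 and with an estimated correlation (adjusted p = 0.00160, 0.00119 and 0.00890 for the risers of 1 h, and 6.05e-05 and 2.54e-04 for those of 6 h, each with an estimated correlation). By single calls, 113 of the 137 risers of 1 h and 34 of the 37 of 6 h rose in CT against CC at 24 h, where independent lists would share 6.74 and 1.82. Of the 29 risers of 24 h, 22 were tested in the triggering set, and 1 of them rose in CT against CC and 7 in PT against PC at 24 h (1.08 and 1.03 for independent lists). Insect RNA can lie on P leaves, with the secretion, and on fed leaves, with the larvae, and both kinds of leaf were wounded. These overlaps thus do not tell a leaf response shared by eggs and larvae from insect RNA or a response to wounding.

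In unfed leaves the same lists lay slightly higher in PC than in CC at 1 h, by a median of 0.52 for the risers of 1 h (89.1% of them higher) and 0.50 for those of 6 h (94.6% higher). Both passed camera with the preset correlation and were lost with an estimated one (adjusted p = 0.357 and 0.133 with an estimated correlation). The 22 risers of 24 h lay higher in PC at 6 h by a median of 1.27, also lost (adjusted p = 0.118 with an estimated correlation). In fed leaves, the risers of 1 h had a median difference between PT and CT of 0.15 at 1 h, 0.00 at 6 h and 0.07 at 24 h (-0.33 at 24 h without CT 24 h replicate 1). At 24 h the risers of 1 h and those of 6 h, with a median of 0.14, were called lower in camera, which sets the test statistics of a list against those of all other transcripts. Both calls were lost with an estimated correlation (adjusted p = 0.650 for each with an estimated correlation). Of 27 such tests, 17 passed with the preset correlation, 5 with an estimated one and 5 in fry, which tests whether a list moves on balance one way.

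The reverse was tested too: whether transcripts that respond to feeding differed with earlier eggs. The lists came from the mean of both feeding responses, with 1441 risers and 289 fallers at 1 h (2319 and 1128 without CT 24 h replicate 1), 4622 and 856 at 6 h (6362 and 2407 without it), and 14466 and 16809 at 24 h. The risers of 1 h lay higher in PT than in CT at 1 h by a median of 0.33 (82.0% of them) and the fallers lower by a median of -0.40. Both were lost with an estimated correlation (adjusted p = 0.288 and 0.0941 with an estimated correlation). Without CT 24 h replicate 1, the fallers passed with an estimated correlation (adjusted p = 0.0313, median -0.31) and the risers did not (adjusted p = 0.264). The 16809 fallers of 24 h were less reduced in PT than in CT, by a median of 0.85 (89.5% higher; adjusted p = 0.565 with an estimated correlation), and by 0.16 without CT 24 h replicate 1. The riser lists were higher soon after simulated eggs, and the faller lists lower at 1 h, with medians of -0.37, -0.14 and -0.10 for those of 1, 6 and 24 h. The faller lists did not pass with an estimated correlation (adjusted p = 0.288, 0.288 and 0.245 with an estimated correlation). The feeding risers of 1, 6 and 24 h had median differences of 1.40, 0.86 and 0.33 in P against C at 1 h, with 97.5%, 88.4% and 77.0% of members higher (adjusted p = 0.0120, 0.0120 and 0.0233 with an estimated correlation). Those of 6 and 24 h had 0.52 and 0.25 at 6 h (adjusted p = 0.0314 and 0.0482 with an estimated correlation). The call of 24 h risers at 6 h was lost with DESeq2 size factors and with the replicate block (adjusted p = 0.0531 and 0.0606 with an estimated correlation). Of 30 such tests, 27 passed with the preset correlation and 5 with an estimated one.

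Because larvae sat on the fed leaves, sequences seen in fed leaves alone were counted. With 0 reads in all 18 unfed libraries and at least 3 reads in each library of a fed group, 172 sequences were found. Of these, 105 were found in CT and 44 in PT at 6 h, 36 in CT and 109 in PT at 24 h, and 0 in CT and 2 in PT at 1 h. The numbers of CT and PT at 24 h cannot be compared, since the rule needs reads in every library of a group and CT 24 h replicate 1 held reads of 62026 sequences. The reverse rule, with 0 reads in the 18 fed libraries, found 0. In the priming set these 172 sequences took a median of 3.65 RPM over the 9 P libraries and 0.195 over the 9 C libraries (2-sided exact permutation test, p = 2.88e-04, adjusted p = 0.00103 over 25 comparisons). The plan had foreseen counts only, so this test was added to it.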

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

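The tests of the feeding response between times, and their repeats without CT 24 h replicate 1, were chosen only after the counts of each time had been seen. Each result below stands out because edgeR's quasi-likelihood test of the difference between times itself called transcripts at a Benjamini-Hochberg adjusted p of at most 0.05.

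In leaves without earlier eggs, the response to larvae (CT against CC) differed between 24 and 1 h for 860 transcripts, 499 of them higher and 361 lower at 24 h, and for 1174 without CT 24 h replicate 1. In leaves with earlier eggs (PT against PC) it differed between the same times for 848, 719 of them higher and 129 lower at 24 h, and for 1766 without that library, which belongs to neither group but shares the estimate of the spread. Between 24 and 6 h it differed for 12 transcripts in CT against CC (3 without CT 24 h replicate 1) and for 3 in PT against PC (4 without it). Between 6 and 1 h it differed for 1 transcript in CT against CC (1 without it) and for 46 in PT against PC, 40 of them higher and 6 lower at 6 h (77 without it). The transcripts behind the smallest counts, named after their values were seen, were C263837 in CT against CC, whose response was higher at 6 than at 1 h by 5.65 ± 0.81 (SE, log2), and C273605, C608167 and C609291 in PT against PC, higher at 24 than at 6 h by 4.79 ± 0.63, 3.34 ± 0.53 and 2.94 ± 0.48 (SE, log2).

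Other splits of the same libraries gave as many calls for each of these differences, so chance was not excluded by this test. For 24 against 1 h, 6 of 21 splits, the real one included, reached 860 in CT against CC (highest other 8600) and 6 of 21 reached 848 in PT against PC (highest other 3971). All 5 of the other splits in each case kept the real fed and unfed labels at 1 of the 2 times, so that the feeding response of that time stood in the difference in full. These large counts point to a structure of the samples, the feeding response itself. For 24 against 6 h, 3 of 21 splits reached 12 in CT against CC (highest other 2589) and 2 of 21 reached 3 in PT against PC (highest other 18). For 6 against 1 h, 3 of 21 reached 1 in CT against CC (highest other 1020) and 3 of 21 reached 46 in PT against PC (highest other 101).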

How the results depend on the processing

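Leaving CT 24 h replicate 1 out of the whole fit, alone or with the replicate block, and leaving P replicate 1 out at all 3 times were tests chosen only after the result was seen. No named transcript and no set test reversed. Without CT 24 h replicate 1, however, CT against CC at 24 h turned from more fallers (8317 against 7442) to more risers (7916 against 6398), and the median difference of the 1 h egg risers in PT against CT at 24 h from 0.07 to -0.33. Among values of named transcripts, 53 stayed past the threshold and 18 lost it under other settings, and 42 stayed and 42 lost it with 1 library left out, all with the direction kept, and among repeated set tests 212 kept their side of it, 8 lost and 8 gained a call. With DESeq2 size factors in edgeR, every count stayed within 1.5 times. Where a count moved, the cause was not tested. Fewer libraries in a fit leave fewer degrees of freedom, but some counts rose when a library was left out. Counts follow as P against C, CT against CC, PT against PC, PC against CC, PT against CT and the interaction, at 1, 6 and 24 h.

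DESeq2's Wald test called 1515, 498 and 234; 556 and 2389 (1 and 6 h); 799 and 3360 (1 and 6 h); 95, 111 and 34; 25, 5 and 245; and 14, 99 and 35. The replicate block gave 448, 100 and 599 for P against C, and 0 and 738 for CT against CC at 1 and 6 h. It gave 4 for PT against PC at 1 h, 2 for PC against CC at 1 h and 0 for PT against CT at 24 h. No other count moved beyond 1.5 times. All same-numbered correlations passed 0.1 in PC against CC at 1 h alone, but comparisons with CC at 6 h shared only 2 numbers and could not meet this bound. Every library correlated best with its own number in 8 of the 15 pairs of groups, so a pairing by number is not excluded in the other comparisons. With the compared groups alone, P against C gave 164 at 6 h and 0 at 24 h, CT against CC 0 at 1 h and 2545 (2061 up, 484 down) at 24 h, PT against PC 0, 4028 and 17917, and PT against CT 0 at 24 h. With no filter, P against C gave 92 at 24 h, PT against PC 0 at 1 h and PT against CT 244 at 24 h. P replicate 1, the least alike of the priming libraries at each time, left out at all 3 times gave 85 at 6 h and 340 at 24 h. CT 24 h replicate 1 left out with the block gave 0 for CT against CC at 1 h, 148 and 2927 for PT against PC at 1 and 6 h, 2 and 1 for PC against CC at 1 and 6 h, and 3 and 0 for PT against CT at 6 and 24 h.

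Leaving out 1 library gave 0 to 261, 0 to 55 and 0 to 738 for P against C, 0 to 245, 555 to 1947 and 8891 to 14913 for CT against CC, 0 to 547, 576 to 3100 and 5177 to 16856 for PT against PC, 0 to 2, 0 to 1 and 0 to 0 for PC against CC, 0 to 0, 0 to 0 and 0 to 627 for PT against CT, and 0 throughout for the interaction. The 200 transcripts with the smallest p gave 29 of 54 egg list tests in place of 17 of 27. Over transcripts called in the mean feeding effect, which selects shared directions, r was 0.76, 0.82 and 0.88. Sequences seen in fed leaves alone numbered 352 (reverse 3) at a minimum of 1 read and 63 (reverse 0) at 10. Without CT 24 h replicate 1, r was 0.30, 0.37 and 0.67, 108 of the 137 risers of 1 h rose in CT against CC at 24 h, and of the risers of 24 h 0 did. Depth was not varied. In data simulated at the real library sizes, 2-fold changes were recovered in 10.0% of cases for P against C at 1 h.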

Other observations

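The rule for sequences tied to the egg treatment, the bounds on their levels in the replicates and at application, the repeats without CT 24 h replicate 1 and the comparison of harvest times were chosen only after the data were seen.

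A total of 1558 sequences had at least 5 CPM in 1 or more P libraries and under 0.1 CPM in the pooled C libraries, while the reverse rule, with C and P exchanged, found 17. By the correlation of their levels, 1529 of them fell into 3 groups. The first, 797 sequences, took 42167, 57.2 and 1533 RPM in the 3 P libraries of 1 h, 31457, 3224 and 777 in those of 6 h, and 176, 46.9 and 18.0 in those of 24 h, against at most 2.12 in any C library. The highest value of each time lay in P replicate 1. The 1558 sequences were chosen on P and C alone, so the triggering set did not enter the rule, while the grouping used the correlations over all 54 libraries. Together the 1558 had a median of 62.0 RPM over 9 PC libraries and 6.70 over 9 CC libraries (2-sided exact permutation test, p = 0.00152, adjusted p = 0.00346 over 25 comparisons), 7 days after the treatment and without larvae. Some of the 25 tests were settled by the choice of sequences, which makes this adjusted p too small. In fed leaves without eggs their median was 240 (2-sided exact permutation test against CC, p = 4.11e-05, the smallest it can give, adjusted p = 1.71e-04). With earlier eggs, fed and unfed leaves did not differ detectably (216 in PT and 62.0 in PC, 2-sided exact permutation test, p = 0.283, adjusted p = 0.417), nor did PT and CT (same permutation test, p = 0.748, adjusted p = 0.891). The first group had medians of 45.7 over PC and 1.88 over CC. The second group, 635 sequences, was most abundant in P at 24 h, with 1141 to 20438 RPM and the highest value again in replicate 1. It stood at 183, 0.528 and 59.9 RPM in PT 24 h replicates 1, 2 and 3 and at 111 in PC 6 h replicate 3, against at most 9.07 in any CC library. Over 9 against 9 libraries it did not differ detectably between PT and PC or between PC and CC (2-sided exact permutation test, adjusted p = 0.375 and 0.846 over 25 comparisons). The third, 97 sequences, stood at 2855 RPM in P 6 h replicate 2 and 1734 in CT 6 h replicate 1.

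The share of reads in the most abundant sequences was not tested between treatments. The 10 most abundant sequences of a library took 25.5% ± 14.7 of the reads in CT at 1 h, 19.3% ± 13.5 at 6 h and 52.8% ± 26.9 at 24 h, and 10.4% ± 4.05, 40% ± 16.5 and 23% ± 12.1 in PT at those times, against 12.1% ± 1.33 to 15.0% ± 1.22 in PC (SD, n = 3 each). Unfed and untreated leaves reached high shares too, with 18.3% ± 13.5 in CC and 19.6% ± 11.4 in C at 6 h (SD, n = 3 each), and 32.6% and 32.7% in replicate 1 of each.

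Harvest time changed many transcripts in untreated leaves. Between 1 and 6 h, 12635 transcripts differed in C and 3706 in CC, and between 6 and 24 h 16166 in C and 1473 in CC. Between 1 and 24 h, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 in both (9163 and 10310 at an unadjusted p of at most 0.05). Among 124863 transcripts tested in both sets, 1954 were called in both C and CC for 6 against 1 h (353 for independent lists), 1952 of them in the same direction, and 1117 for 24 against 6 h (185 for independent lists), all in the same direction. Clock times of harvest are not given in the sources used here.

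The first group of sequences at 1 and 6 h, near 0 in untreated leaves and abundant in single treated leaves, was weighed first. A single source of fixed makeup, brought onto the leaf, would keep the order of levels among its sequences. The test used 698 sequences above 5 CPM in P 1 h replicate 1 and under 0.1 CPM in the pooled C libraries, not the group itself. Their rank correlation with P 1 h replicate 1 had a median of 0.41 over the other 5 P libraries of 1 and 6 h (0.30 to 0.78). This lay under the bound of 0.5 set in advance, which argues against it. Ties at 0 reads can lower the 0.30 of P 1 h replicate 2, where 37.5% were detected. P 1 h replicate 3 and P 6 h replicate 2, with 88.1% and 84.0% detected, had 0.41 and 0.37. P 6 h replicate 3, with 76.9%, had 0.65. A response of the leaf stays open: the 3 P libraries of 1 h ranged 737-fold, but the rule admitted sequences abundant in 1 P library, so a wide range was built into the choice. More than 1 source, or 1 whose makeup varies, may stand behind it: P 6 h replicate 2 had a rank correlation of 0.85 with CT 6 h replicate 1 but 0.37 with P 6 h replicate 1. P 1 h replicate 1 had 0.78 with P 6 h replicate 1 and 0.75 with PC 6 h replicate 1.

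For the second group, abundant at 24 h, a source of fixed makeup that increased on the treated site, such as microorganisms on the wound, is a candidate explanation: over sequences chosen on P 24 h replicate 1 alone, the rank correlation with the other 2 P libraries of 24 h had a median of 0.89. Of these 643 sequences, 99.4% and 99.8% were detected in those 2 libraries, and 1.56% to 70.3% in the 6 P libraries of 1 and 6 h. RNA brought with the secretion at application is not excluded by this, since each time was taken from other leaves, and whether they received the same secretion is not given in the sources used here. The group itself was formed by its levels over the libraries, so its highest level at 1 and 6 h, 63.5 RPM, decides nothing. A response of the leaf cannot be told apart from these either, with a 17.9-fold range between the replicates.

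The 52 transcripts lower in PT than in CT at 24 h were weighed last. Without CT 24 h replicate 1 the count was 0. It was also 0 without any 1 PT library, so the count by itself does not single out CT 24 h replicate 1. That replicate held 99.95% of the CT reads of the median called transcript, which points to its makeup as the source. An effect of earlier eggs in all libraries was argued against, since the median log2 fold change of the 52 transcripts was -0.29 without that library and -13.87 with it, and 1 of them had an unadjusted p of at most 0.05. Low depth outside its 10 most abundant sequences did not account for its makeup either: thinned to the reads that it held outside them, the other 5 fed libraries of 24 h each detected at least 1.84 times as many sequences. What the abundant sequences of that library are stays open.

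The 6 libraries of a comparison can be split in 10 ways, the real one included, so a share under 0.05 cannot be reached. The real count and the highest of the other splits were 139 and 0 for P against C at 1 h, 37 and 0 at 6 h and 29 and 0 at 24 h. They were 3 and 0, 1451 and 0, and 15759 and 934 for CT against CC, and 1 and 199, 1763 and 0, and 11290 and 0 for PT against PC. At 1 h, 4 of the 10 splits of PT and PC gave at least 1 call, and a split with 199 points to a structure of the samples. PC against CC gave 0 in all 10 splits at each time, and PT against CT gave 0 and 81, 0 and 0, and 52 and 54, where 3 of 10 splits reached 52 at 24 h. For harvest time, the values were 12635 and 0, 16166 and 0, and 0 and 0 in C, and 3706 and 0, 1473 and 0, and 0 and 0 in CC, for 6 against 1 h, 24 against 6 h and 24 against 1 h. For the interaction, the real count of 0 is reached by any split, so that all 21 splits, the real one included, reached it decides nothing. The highest other count was 83, 0 and 1 at 1, 6 and 24 h, and the 83 points to a structure of the samples.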
